A study of Mus musculus with 2 samples.

How the data were processed

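RNA was measured by sequencing of polyadenylated RNA from 2 libraries of mouse embryonic liver at day 14, which form 1 group, per the labels. The expected count values, estimated fragments per gene or transcript, were made by the authors from an alignment to the transcriptome of mm10 with the GENCODE M4 annotation, and the aligner and quantifier are not given in the sources used here. The TPM values were deposited beside them, scaled by the authors so that each library sums to the same total with the spike-ins included. The FPKM values were likewise made by the authors per kilobase of effective length. The score values used are, per the file headers, the posterior SD of each count, and, in the junction and contig lists, a significance field deposited by the authors that was read as an irreproducibility value. The junction counts were deposited as whole numbers of reads over each mm9 junction, and the sum of both replicates' reads equalled the listed total for every junction. The contig signal was deposited as a level per contig, made by the authors for both replicates together, and its values behaved as bases per kilobase per amount of mapped bases. The mm9 gene values were deposited as RPKM of replicates that the table does not name, for ENSEMBL genes and for Cufflinks models. The mm9 exon and transcript values are not used here, apart from exon positions.

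Counts on the ERCC spike-ins, on phiX174 and on 26248 features named by numbers alone were set apart, which left 43346 genes, of which 42462 were matched by identifier to GENCODE M21 symbols, biotypes and GRCm38 positions. Of 339 listed gene symbols, 4 had no match and carry no value. Positions on mm9 come from the mm9 tables and were not converted. The libraries held 100477392 and 154601605 expected counts, so that 3 counts, the upper limit that a count of 0 allows, are 2.99e-06% and 1.94e-06% of them. Intervals for shares are exact Clopper-Pearson intervals at 95%.

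Agreement was computed on log2(TPM + 0.1). The biological coefficient of variation is the square root of the common dispersion of edgeR 4.0.16 with an intercept alone and TMM scaling, over genes with at least 10 counts in total. Each gene was compared between the libraries by a two-sided exact conditional binomial test on rounded expected counts with TMM effective library sizes, adjusted by Benjamini-Hochberg at 0.05, and ratios carry exact counting intervals. The 25 marker lists were fixed before the data were examined: adult globins, embryonic globins, erythroid, heme synthesis, iron handling, fetal hepatocyte, mature hepatocyte, cholangiocyte, stellate and mesenchymal, endothelial, macrophage, neutrophil and granulocyte progenitor, megakaryocyte, stem and progenitor, B lymphoid, T and NK, mast cell with basophil and eosinophil, niche factors, S phase, mitosis, imprinted, fetal RNA-binding and chromatin, sex chromosome, stress response, and adjacent tissue. A list's level is the median TPM of its members per library, set against 10000 random protein-coding lists of its size, and its difference between the libraries is the median log2 ratio of members with at least 10 counts, set against random lists drawn from the 100 genes on each side of every member in mean expression. A further 8 lists were added after the data were seen: skeletal muscle, epidermis, cartilage and bone, heart, nervous system, gut and pancreas, trophoblast, and interferon response.

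The genes named were set by a rule written before the data were examined: the 20 with the highest mean TPM, mitochondrially encoded genes and spike-ins apart; of each fixed list the 4 highest members and the lowest, and all globin and sex chromosome members; the 10 protein-coding genes with the largest ratio in each direction among those past the threshold with a mean of at least 50 counts; list members past the threshold with an absolute log2 ratio of at least 1; and list genes of at least 100 TPM whose highest transcript held the smaller part of the gene. Some genes that the rule names are not reported here. Main transcripts were compared for genes with at least 5 TPM in both libraries. Junctions and contigs were placed against ENSEMBL exons and genes of mm9 on the same strand with bedtools 2.31.1, with an overlap of at least 1 base.

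The gene test was tested on simulated data with 200 changed genes. With counting error alone it found 94 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and called 8 of 18441 unchanged genes. With a biological coefficient of variation of 0.1 added it called 7739 of 18409 unchanged genes, 56 of them at 2-fold or more, so that its calls describe the libraries and not the tissue. Alternatives were DESeq2 1.42.0 size factors or library totals for TMM, other filters, pseudocounts and thresholds, FPKM or mm9 RPKM for TPM, means for medians, each replicate left out, and a negative binomial exact test. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.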

Results

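Polyadenylated RNA longer than 200 nucleotides was sequenced from the liver of C57BL/6J mouse embryos at day 14 of gestation, a stage at which the liver is the main site of blood formation and its hepatocytes are still immature. The series holds 1 group of 2 libraries, labelled as biological replicates 1 and 2, each from pooled male and female littermates and each sequenced as stranded paired reads. Both carry the same donor entry, and nothing in the labels says that the pools came from separate litters, so the spread between them is not known to cover differences between litters. The expected counts summed to 100477392 in replicate 1 and 154601605 in replicate 2, of which 97174777 and 149348514 were on mouse genes. Intervals and upper limits for 0 counts (3 counts per library) cover counting error only. There was no second condition, so the comparisons are between gene groups within the profile, between the 2 libraries, and between the newer mm10 tables and the older mm9 tables of the same series. Expression levels are given as mean TPM ± SD with n = 2 libraries throughout, and coordinates of mm10 genes are GRCm38 positions. With 2 libraries in 1 group no test between groups exists, and no exact test of 2 values can reach p = 0.05.

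The liver profile was led by the adult globins and by secreted hepatocyte proteins. Hba-a2, an adult alpha-globin gene, had the highest level at 191316 ± 16054 TPM (ENSMUSG00000069917.7, chromosome 11, 32296489 to 32297298). The adult beta-globin genes Hbb-bs (141824 ± 5592 TPM, chromosome 7, 103826534 to 103828096) and Hbb-bt (78305 ± 4900.1 TPM, chromosome 7, 103812524 to 103813996) and the alpha-globin gene Hba-a1 (50638 ± 7279 TPM, chromosome 11, 32283511 to 32284465) came next. Alb, which encodes serum albumin, reached 9776 ± 939 TPM (chromosome 5, 90460897 to 90476602), and Afp, its fetal relative alpha-fetoprotein, reached 7244 ± 772 TPM (chromosome 5, 90490737 to 90508907). These 4 adult globin genes took 46.2 ± 3.38% of all TPM and 24.7 ± 2.83% of the expected counts on genes. The 10 highest entries, with mitochondrial genes, spike-ins and phiX174 among the candidates, took 53.6 ± 2.70% of TPM, or 30.9 ± 1.74% of expected counts. Without mitochondrial genes and spike-ins, the 10 highest genes took 54.5 ± 2.83% of the TPM that remained.

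Among the 20 highest nuclear genes were the translation genes Rplp1 (5378 ± 116 TPM), Rps12 (5023 ± 54.7 TPM), Eef1a1 (3905 ± 95.5 TPM), Rpl41 (2453 ± 319 TPM), Rps24 (2100.1 ± 82.8 TPM) and Rplp0 (2046 ± 88.6 TPM). Gpx1, a selenium-dependent peroxidase, stood at 3236 ± 268 TPM, the imprinted non-coding RNA H19 at 2862 ± 54.0 TPM (chromosome 7, 142575529 to 142578143), the metallothionein Mt1 at 2168 ± 369 TPM, the apolipoprotein Apoa2 at 2515 ± 144 TPM and Trf, the iron carrier transferrin, at 2099 ± 145 TPM. The remaining 3 were annotated as non-coding or as a pseudogene. Gm10076 had 4193 ± 466 TPM and Gm29216 3640.0 ± 166 TPM. Gm42418 (chromosome 17, 39846958 to 39848788) differed most between the libraries, at 1812 TPM in replicate 1 and 7827 TPM in replicate 2. Of the mitochondrially encoded genes, mt-Co2 (3330.4 ± 244 TPM), mt-Co1 (2709 ± 531 TPM), mt-Co3 (2071 ± 6.14 TPM) and mt-Atp6 (1977 ± 49.1 TPM) lay in the range of the highest nuclear genes. The value of mt-Atp8, 36706 ± 1618 TPM, came from 38051 and 50993 expected counts divided by very short effective lengths (8.63 nucleotides in replicate 1), and by counts it ranked 280th among genes.

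A TPM of at least 1 in both libraries was reached by 11526 genes, of which 10858 were protein-coding, 239 processed pseudogenes, 86 long intergenic non-coding RNAs and 78 antisense genes. A further 195 genes passed in replicate 1 alone and 305 in replicate 2 alone. At 100 TPM, 635 genes passed in both libraries, and at 1000 TPM 72 did. Protein-coding genes took 93.9% of TPM in replicate 1 and 92.4% in replicate 2.

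Adult globins far exceeded embryonic ones. The embryonic beta-type genes Hbb-y (425 ± 107 TPM, chromosome 7, 103851749 to 103853216) and Hbb-bh1 (199 ± 3.67 TPM, chromosome 7, 103841637 to 103843164), which are characteristic of the primitive red cells of the yolk sac, made up 0.192% ± 0.0392 and 0.0904% ± 0.00600 of beta-globin TPM, and the embryonic alpha-type gene Hba-x (29 ± 3.15 TPM, chromosome 11, 32276400 to 32278116) made up 0.0120% ± 0.000148 of alpha-globin TPM. The log2 ratio of adult over embryonic TPM was 8.47 ± 0.17 for beta-globins and 13.03 ± 0.02 for alpha-globins (SD, n = 2). Summed adult alpha-globin TPM exceeded summed adult beta-globin TPM 1.10 ± 0.0537-fold. Within pairs, Hba-a2 exceeded Hba-a1 3.79 ± 0.228-fold and Hbb-bs exceeded Hbb-bt 1.81 ± 0.0420-fold. The members of each pair are nearly identical in sequence, so their split is uncertain and their sums are the firmer values, although the deposited posterior SD of the Hba-a2 count in replicate 1 was 1786 fragments.

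Red cell genes were high as a group. The erythroid list had a median of 137 ± 27.3 TPM, above all 10000 random protein-coding lists of its size, and all 29 measured members exceeded 10 TPM in both libraries. Among the highest were Car2, a carbonic anhydrase (1269 ± 129 TPM), Alas2, the erythroid first enzyme of heme synthesis (894 ± 66.5 TPM) and Slc4a1, the band 3 anion exchanger (491 ± 56.6 TPM). The lowest was Car1, at 15.2 ± 3.08 TPM. The heme synthesis list had a median of 244 ± 31.4 TPM, with Urod at 396 ± 29.7 TPM and Alad at 248 ± 32.5 TPM, while Alas1, the housekeeping counterpart of Alas2, was lowest at 16.3 ± 2.21 TPM. The iron handling list had a median of 32.6 ± 2.96 TPM. The ferritin chains Fth1 (1577 ± 156 TPM) and Ftl1 (1460.3 ± 282 TPM) and the mitochondrial iron importer Slc25a37 (439 ± 102 TPM) followed Trf in it. Hamp2 had 0 counts in both libraries, which allows up to 0.110 TPM in replicate 1 and 0.0771 TPM in replicate 2. The heme synthesis and iron handling lists also lay above all random lists.

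The fetal hepatocyte list was high and most genes of the mature hepatocyte list were low. The fetal hepatocyte list had a median of 255 ± 18.4 TPM, above all random lists, led by Alb, Afp, Apoa2 and Trf; its lowest member was Amn at 0.715 ± 0.0212 TPM. The mature hepatocyte list had a median of 0.495 ± 0.120 TPM, at the 21.8 percentile of random lists, and 13 of 30 members reached 1 TPM in both libraries. Among the highest of these were Glul, glutamine synthetase (80.2 ± 3.44 TPM), Ass1 of the urea cycle (61.6 ± 8.11 TPM) and Bhmt of methionine metabolism (29.1 ± 1.68 TPM). Cyp2c29 and Mup3 had 0 counts, which for Mup3 allows up to 0.0332 TPM in replicate 1 and 0.0230 TPM in replicate 2. The log2 ratio of the medians, fetal over mature list, was 9.03 ± 0.25 (SD, n = 2). This ratio contrasts 2 gene lists and not 2 ages, since no adult liver was measured. It was 4.05 when members under 1 TPM were left out. The median of the erythroid list was below that of the fetal hepatocyte list, with a log2 ratio of -0.91 ± 0.19, and the difference of the lists' mean log2(TPM + 0.1) was -0.07.

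**Figure D1:**
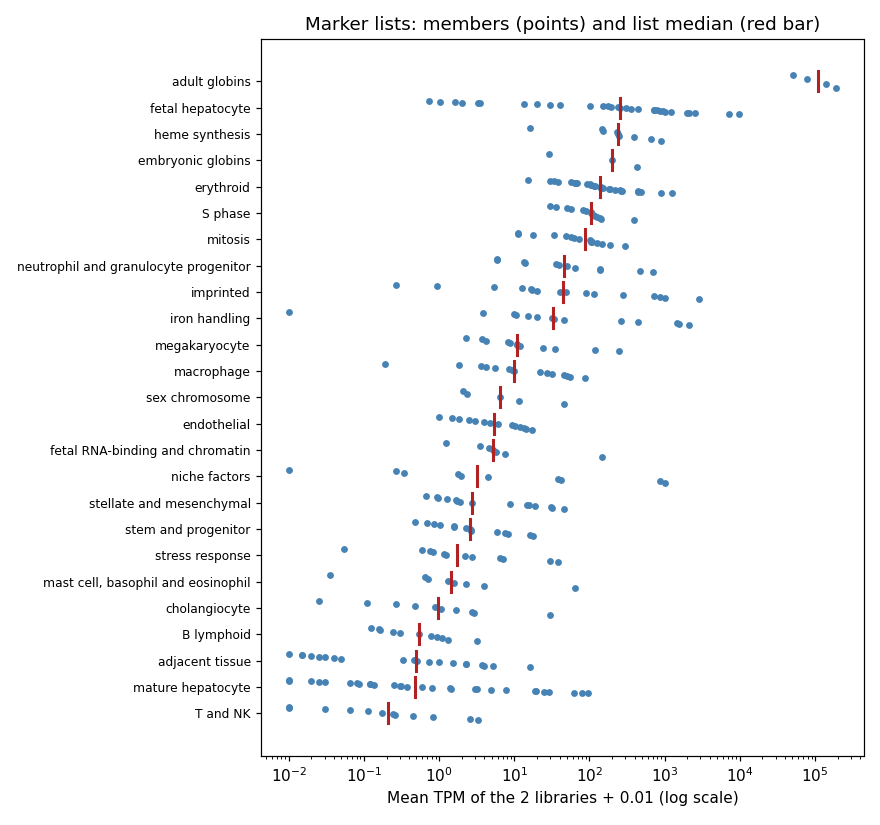
Mean TPM of the members of the 25 marker lists fixed before the data were examined, over the 2 embryonic liver libraries, with 0.01 added for the log axis. Each point is a gene and each red bar a list median; the adult globins lie at the right end, and the T and NK list has the lowest median, 0.190 ± 0.00707 TPM.

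Of the other blood lineages, granulocyte genes stood highest. The neutrophil and granulocyte progenitor list had a median of 45.3 ± 15.7 TPM, with the calcium-binding proteins S100a8 (702 ± 199 TPM) and S100a9 (470.3 ± 118 TPM), the granule enzymes Mpo (139 ± 20.3 TPM) and Prtn3 (137 ± 32.9 TPM) highest, and the transcription factor Cebpe and lactoferrin, Ltf, lowest, each with a mean of 5.92 TPM. The megakaryocyte list had a median of 10.9 ± 0.721 TPM: Pf4 (245 ± 13.1 TPM) and Ppbp (119 ± 14.5 TPM), chemokines of platelet granules, led it, before Itga2b (34.3 ± 0.948 TPM) and Gp9 (24.3 ± 0.247 TPM), and Gp6 was lowest at 2.25 ± 0.474 TPM. The macrophage list had medians of 8.16 TPM in replicate 1 and 11.9 TPM in replicate 2, with Lyz2 (86.2 ± 19.3 TPM), the complement gene C1qb (48.3 and 62.5 TPM), Cd5l (51.0 ± 10.8 TPM) and the iron exporter Slc40a1 (45.6 ± 9.07 TPM) highest and Vsig4 lowest (0.180 ± 0.0424 TPM). In the mast cell, basophil and eosinophil list, with a median of 1.42 ± 0.124 TPM, Prg2, an eosinophil granule protein, stood apart at 65.2 ± 10.3 TPM; Epx (3.90 ± 0.587 TPM), Cpa3 (2.27 ± 0.106 TPM) and Gata2 (1.56 ± 0.141 TPM) followed and Fcer1a was lowest (0.0250 ± 0.00707 TPM). The stem and progenitor list had a median of 2.55 ± 0.750 TPM, with Spi1 (17.6 ± 2.86 TPM), Myb (16.3 ± 1.20 TPM), Kit (8.12 ± 0.233 TPM) and Cd34 (7.44 ± 0.127 TPM) highest and Hoxa9 lowest (0.475 ± 0.0354 TPM). Lymphoid genes were scarce. The B lymphoid list had a median of 0.535 ± 0.134 TPM, from Cd79b (3.14 ± 0.891 TPM), Igll1 (1.29 ± 0.304 TPM), Vpreb1 (1.08 ± 0.0919 TPM) and Cd79a (0.935 ± 0.148 TPM) down to Pax5 (0.115 ± 0.0495 TPM). The T and NK list was led by Lck (3.29 ± 0.332 TPM), Nkg7 (2.60 ± 0.863 TPM), Trbc2 (0.830 ± 0.184 TPM) and Trbc1 (0.440 ± 0.0141 TPM), and Cd3e and Cd8a had 0 counts, which for Cd8a allows up to 0.00835 TPM in replicate 1 and 0.00577 TPM in replicate 2. Among random lists the granulocyte median lay above all 10000, and the others at the percentiles 98.4 (macrophage), 98.3 (megakaryocyte), 71.7 (stem and progenitor), 48.6 (mast cell, basophil and eosinophil), 34.8 (B lymphoid) and 16.4 (T and NK).

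The lists for supporting cells of the liver and for niche factors had moderate medians. The endothelial list had a median of 5.42 ± 0.297 TPM, at the 90.5 percentile, and its highest members, Stab1 (17.5 ± 1.54 TPM), Oit3 (14.3 ± 1.10 TPM), Lyve1 (13.7 ± 1.53 TPM) and Eng (11.9 ± 1.70 TPM), include genes typical of liver sinusoids; Flt1 was lowest at 1 ± 0.127 TPM. The stellate and mesenchymal list had a median of 2.71 ± 0.156 TPM, at the 73.8 percentile, with the collagen gene Col3a1 (46.1 ± 17.2 TPM), Reln (32.1 ± 4.48 TPM), the proteoglycan Dcn (30.6 ± 3.02 TPM) and Col1a2 (18.8 ± 10.2 TPM) highest and Lrat lowest (0.655 ± 0.0636 TPM). The cholangiocyte list, with a median of 0.955 ± 0.0707 TPM at the 40.1 percentile, was led by Tspan8 (30.1 ± 2.57 TPM), then Spp1 (2.90 ± 0.672 TPM) and Krt19 (2.74 ± 2.06 TPM), and Cftr was lowest at 0.0150 ± 0.00707 TPM. Among niche factors (median 3.29 ± 0.191 TPM, percentile 72.9), Dlk1 (1022 ± 119 TPM) and the growth factor Igf2 (876 ± 26.0 TPM) were far above the chemokine Cxcl12 (38.6 ± 3.15 TPM). Dlk1 and Igf2 are also members of the fetal hepatocyte and imprinted lists. Fgf21 had 0 counts, which allows up to 0.0339 TPM in replicate 1 and 0.0235 TPM in replicate 2.

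Proliferation genes were high. The S phase list had a median of 106 ± 8.53 TPM and the mitosis list one of 85.8 ± 9.18 TPM, both above all random lists, and all members of both exceeded 10 TPM in both libraries. Pcna, the sliding clamp of DNA replication, reached 387 ± 15.4 TPM, before Mcm7 (140.4 ± 4.65 TPM), Rrm2 (123 and 157 TPM) and Tk1 (126 ± 13.2 TPM), with Cdc6 lowest (30.3 ± 0.969 TPM). The kinase gene Cdk1 reached 296 ± 29.9 TPM, Birc5 189 ± 15.0 TPM, and the cyclin genes Ccna2 and Ccnb1 147 ± 15.8 and 128 ± 13.3 TPM, while Cenpe was lowest at 11.2 ± 0.0707 TPM. The imprinted list had a median of 44.7 ± 4.79 TPM, above all random lists, with H19, Dlk1, Igf2 and Meg3 (720.1 ± 2.17 TPM) highest and Kcnq1ot1 lowest (0.255 ± 0.00707 TPM). Of the fetal RNA-binding and chromatin genes (median 5.21 ± 0.389 TPM, percentile 81.9), Hmga1 was far ahead at 149 ± 1.53 TPM; Igf2bp3 (7.57 ± 0.382 TPM), Lin28b (5.73 ± 0.608 TPM) and Hmga2 (5.21 ± 0.389 TPM) followed and Lin28a was lowest at 1.21 ± 0.226 TPM. The stress response list had a median of 1.80 ± 0.421 TPM at the 56.2 percentile, with Dnajb1 (38.4 ± 5.28 TPM), Ddit3 (29.6 ± 2.71 TPM), Junb (7.14 ± 0.269 TPM) and Ier2 (6.50 ± 1.58 TPM) highest and Fosb lowest (0.0450 ± 0.0212 TPM).

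Between the 2 libraries most genes matched closely, and muscle genes and the sex-linked genes were among those that stood apart. Myh3, the embryonic myosin heavy chain of skeletal muscle, was at 4.47 TPM in replicate 1 and 0.0800 TPM in replicate 2, a log2 ratio (replicate 2 over replicate 1) of -5.92 (95% counting interval -6.24 to -5.60). Actc1, the cardiac and embryonic muscle actin, had a mean of 16.0 ± 20.6 TPM, with a log2 ratio of -4.52 (95% counting interval -4.68 to -4.36). Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), was at 72.4 TPM in replicate 1 and 18.1 TPM in replicate 2, with a log2 ratio of -1.86 (95% counting interval -1.88 to -1.84). The Y-linked genes went the other way. Eif2s3y, Uty and Ddx3y had log2 ratios of 1.85, 1.65 and 1.51, and Kdm5d was at 0.910 and 3.20 TPM. Across 43346 genes the libraries had a Pearson r of 0.994 and a Spearman rho of 0.960 for log2(TPM + 0.1); these are across genes, which are not independent replicates. Of 14525 genes with at least 100 counts in total, 94.2% differed by less than 1.5-fold.

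**Figure D2:**
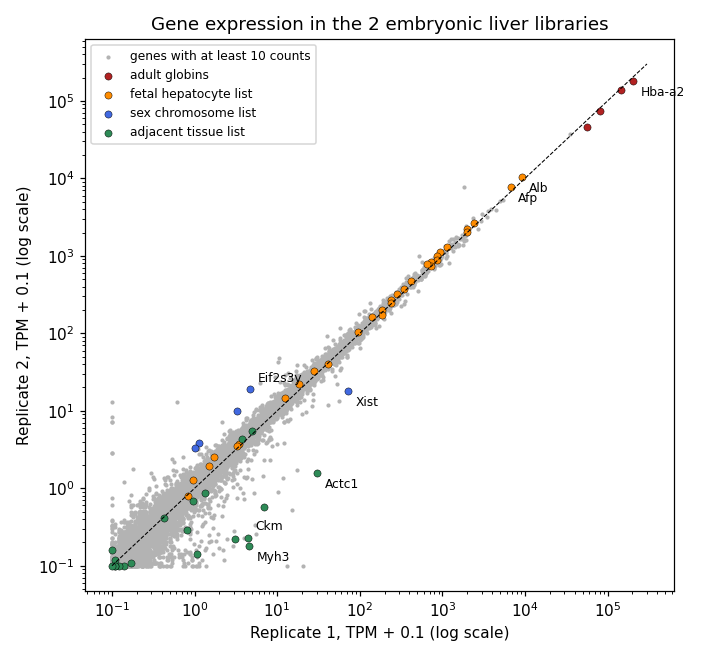
TPM of each gene with at least 10 counts in replicate 1 (horizontal) and replicate 2 (vertical), both with 0.1 added and on log axes, with members of 4 marker lists in colour; the dashed line marks equal values. Tnnt2 lies below the line at 6.87 TPM in replicate 1 against 0.470 TPM in replicate 2, and Eif2s3y above it at 4.56 against 18.9 TPM.

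An exact conditional binomial test of the rounded expected counts, two-sided and with Benjamini-Hochberg adjustment at 0.05, found 7403 of 18572 genes to differ between the libraries beyond counting error, 3661 higher in replicate 2 and 3742 higher in replicate 1. Among them, 881 were at least 2-fold higher in replicate 1 and 177 at least 2-fold higher in replicate 2. The test compares these 2 libraries, not conditions, and it takes counting error as the only error. With the dispersion that edgeR estimates from the same pair, a biological coefficient of variation of 0.191, a negative binomial exact test left 471 genes, 430 higher in replicate 1 and 41 higher in replicate 2; the differences under test set the error of this test. The chi-square of the 2 libraries' counts was 1810416 on 18571 degrees of freedom, beyond counting noise. This does not show that the pools were independent, and they count as 2 samples by their labels. Ratios are scaled by TMM, under which the median log2 ratio of genes with at least 100 counts was 0.01; for unscaled TPM it was 0.15, so genes such as Hbb-bh1, Apoa2 and Igf2, with small negative scaled ratios, have slightly higher TPM in replicate 2.

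The 10 protein-coding genes with the largest ratios in favour of replicate 1 included genes of striated muscle: Myh8 (log2 ratio -6.84), Myh3, Ttn (-5.69), Myl3 (-5.46), Myl1 (-5.38) and Chrng, the fetal subunit of the muscle acetylcholine receptor. Chrng rests on 216 counts against 1, with a log2 ratio of -8.43 (95% counting interval -13.74 to -5.94). The others were Gabrp, a GABA receptor subunit (391 counts against 1, log2 ratio -9.29, interval -14.59 to -6.80), Ablim3 (172 against 3 counts, log2 ratio -6.52, interval -8.81 to -4.95), Mylk4 (-5.65) and the pancreatic protease precursor gene Ctrb1 (-5.39). In favour of replicate 2 stood 2210418O10Rik (4.65), the placental genes Psg21 (2.52), Tpbpb (2.21), Psg23 (2.00), Prl3b1 (2.00) and Tpbpa (1.79), the interferon-induced gene Oas3 (1.66), and the Y-linked Eif2s3y, Uty and Ddx3y. The placental genes were low, with Tpbpa at 0.630 and 2.40 TPM, and Psg21 and Psg23 belong to a family of similar copies whose counts are uncertain.

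Members of the fixed lists with at least a 2-fold difference past the threshold came most often from the adjacent tissue list, which holds muscle, heart, pancreas and other genes of organs next to the liver. In the adjacent tissue list, 11 of 15 tested members were higher in replicate 1 and 0 higher in replicate 2, and 11 and 0 when adjusted over the list alone. Its highest members by TPM were Actc1, Gata4 (5.13 ± 0.410 TPM), Cela1 (3.96 ± 0.417 TPM) and Tnnt2 (6.87 and 0.470 TPM), and Cdx2 was lowest, with 0 and 1 counts. The ratios of Ckm, Myh7, Myog and Tnnt2 were -5.26, -4.76, -4.74 and -3.95, and those of Myh6 and Cpa1 were -2.83 and -1.51. Pdx1 rested on 10 counts against 1, with a log2 ratio of -4.00 (95% counting interval -9.44 to -1.18). Connective tissue and duct genes were also higher in replicate 1: Col1a1 (-1.36), Col1a2 (-1.33), Des (-1.32), Col3a1 (-1.07), Krt19 (-1.68) and Epcam (-1.23). The same held for Fosb (-1.32), Trib3 (-1.31), the iron hormone gene Hamp (-1.05) and Hoxa9 (-1.05). Klrb1c was higher in replicate 2, at 1.15.

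As groups, the granulocyte, macrophage, erythroid and B lymphoid lists lay slightly toward replicate 2, and the embryonic globins and the stellate and mesenchymal list toward replicate 1. The median log2 ratio of the granulocyte list was 0.47 (random lists -0.07 to 0.09), with 12 of 12 tested members higher in replicate 2 and 0 higher in replicate 1, from 0.22 for Mpo to 0.63 for Camp, an antimicrobial peptide gene that was chosen after its value was seen. The macrophage list had a median of 0.23 (random lists -0.07 to 0.09), with 12 of 15 tested members higher in replicate 2 and 2 higher in replicate 1, and the erythroid list one of 0.12 (random lists -0.07 to 0.04), with 27 of 29 tested members higher in replicate 2 and 0 higher in replicate 1. The iron handling list, at 0.10 (random lists -0.12 to 0.07), had 10 of 13 tested members higher in replicate 2 and 2 higher in replicate 1, and the fetal hepatocyte list, at 0.05 (random lists -0.13 to 0.02), had 17 of 31 tested members higher in replicate 2 and 8 higher in replicate 1. Both lymphoid lists lay above their random range too, B lymphoid at 0.40 (random lists -0.36 to 0.21) with 4 of 11 tested members higher in replicate 2 and 0 higher in replicate 1 and T and NK at 0.30 (random lists -0.48 to 0.24) with 2 of 9 tested members higher in replicate 2 and 0 higher in replicate 1, but over the T and NK members with at least 100 counts the median was 0.08, inside the random range. The sex chromosome list had a median of 1.51 (random lists -0.15 to 0.16). On the other side, the stellate and mesenchymal list had a median of -0.49 (random lists -0.09 to 0.10), with 2 of 15 tested members higher in replicate 2 and 11 higher in replicate 1, although its median TPM was 2.60 in replicate 1 and 2.82 in replicate 2. The adjacent tissue list was at -2.77 (random lists -0.20 to 0.13). The stress response list, at -0.40 (random lists -0.13 to 0.12), had 2 of 12 tested members higher in replicate 2 and 8 higher in replicate 1, the imprinted list, at -0.12 (random lists -0.11 to 0.07), had 2 of 16 tested members higher in replicate 2 and 12 higher in replicate 1, and the embryonic globins, at -0.37 (random lists -0.21 to 0.15), had 0 of 3 tested members higher in replicate 2 and 3 higher in replicate 1. In all, 13 of the 25 lists lay outside the range that held 95% of 10000 random lists matched on mean expression, 8 above and 5 below, which describes these libraries and is not a test of conditions.

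The other 12 lists lay within their random range, which for the adult globins decides nothing, since few genes other than themselves are as highly expressed. Their median log2 ratios were -0.30 for adult globins, 0.06 for heme synthesis, 0.05 for mature hepatocyte, -0.21 for cholangiocyte (-0.52, outside the range, over members with at least 100 counts), 0.02 for endothelial, 0.02 for megakaryocyte, 0.02 for stem and progenitor, 0.04 for mast cell, basophil and eosinophil, 0.02 for niche factors, 0.00 for S phase, 0.01 for mitosis and -0.03 for fetal RNA-binding and chromatin genes. The members past the threshold, higher in replicate 1 and higher in replicate 2, were 4 and 0 of 4 adult globins, 0 and 7 of 9 heme synthesis genes, 3 and 5 of 26 mature hepatocyte genes, 5 and 0 of 10 cholangiocyte genes, 4 and 3 of 14 endothelial genes, 2 and 3 of 12 megakaryocyte genes, 4 and 5 of 15 stem and progenitor genes, 1 and 2 of 7 mast cell, basophil and eosinophil genes, 3 and 2 of 9 niche factor genes, 2 and 1 of 7 fetal RNA-binding and chromatin genes, 5 and 7 of 15 S phase genes and 5 and 7 of 16 mitosis genes. Adjusted over the list alone, the counts of the 25 lists were as over all genes except for endothelial (5 higher in replicate 1), S phase (6 higher in replicate 1), imprinted (13 higher in replicate 1) and mature hepatocyte (4 higher in replicate 2).

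**Figure D3:**
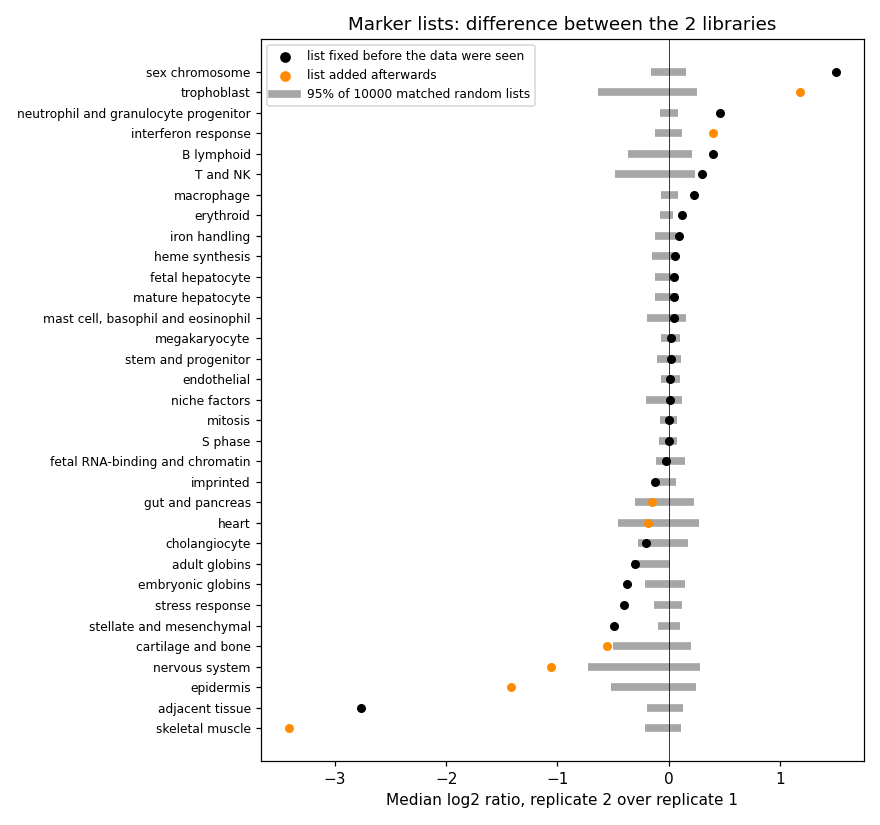
Median log2 ratio, replicate 2 over replicate 1, of each marker list (points; black for lists fixed before the data were examined, orange for lists added afterwards), with grey bars for the range of 95% of 10000 random lists matched on mean expression. The adjacent tissue list lies at -2.77 and the sex chromosome list at 1.51.

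Most genes used the same main transcript in both libraries. Of 5507 genes with at least 5 TPM in both and 2 or more annotated transcripts, 5256 (95.4%) had the same highest transcript, which held a median of 70.9% of the gene's TPM in replicate 1 and 72.0% in replicate 2. Of 54 list genes with at least 100 TPM and 2 or more transcripts, 9 had a highest transcript with less than 50% of the gene. Apoa2 was split evenly between Apoa2-201 (49.9% ± 0.341) and Apoa2-204 (48.0% ± 0.302), both coding. In Trf the highest was Trf-209, annotated as a retained intron (36.5% ± 3.45), ahead of the coding Trf-203 (33.7% ± 4.25); the order of these was reversed in replicate 2. Alas2 was led by the coding Alas2-201 (47.6% ± 3.66), Igf2 by the processed transcript Igf2-208 (45.1% ± 1.72), Meg3 by Meg3-204 (36.5% ± 1.47) and Kel, a blood group antigen gene, by Kel-201 (48.5% ± 1.17). For Uros, Ppox and Epb42 the highest transcripts held 42.2% ± 0.569, 42.4% ± 2.15 and 23.2% ± 0.498. In Epb42 the order was reversed in replicate 1, where Epb42-201 was above Epb42-202. These shares rest on the authors' division of reads among overlapping transcripts.

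The older mm9 gene table ranked genes much as the mm10 tables did, but many ribosomal protein genes had lower values relative to other genes, and adult globins differed between its replicates. Across 33068 genes joined by identifier, mean RPKM in mm9 and mean TPM in mm10 had a Spearman rho of 0.945 and a Pearson r of 0.940 on the log2(value + 0.1) scale. For 20175 protein-coding genes rho was 0.980, and for 4984 pseudogenes it was 0.713. The mm9 table gives 2 values per gene for replicates it does not name. Hbb-bs had an RPKM of 2077 in the first and 13867 in the second (mm9 chromosome 7, 110975048 to 110976610), Hbb-bt 1186 and 8921, Hba-a1 2221 and 13807, and Hba-a2 4554 and 10809. The second value of 8259 well-measured genes was 1.30 times the first at the median, and within 0.994 to 1.75 times for 95% of them. Mean TPM was 4.45 times mean RPKM for the median protein-coding gene, 5.17 times for Alb, 6.32 times for Hba-a1, 15.5 times for Hbb-bt, 17.8 times for Hbb-bs and 24.9 times for Hba-a2, where the globin means pool the unequal values above. Rps12 was at 2.40 and 3.22 RPKM in mm9, and 53 of 75 ribosomal protein genes with at least 100 TPM in mm10 lay more than 4-fold lower relative to other genes than in mm10, while 249 of 271 pseudogenes with at least 10 RPKM in mm9 lay more than 4-fold higher; each group was chosen by the values of the list where it is higher, which favours such a difference. All 37 mitochondrial genes of the mm9 table were listed at 0.

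**Figure D4:**
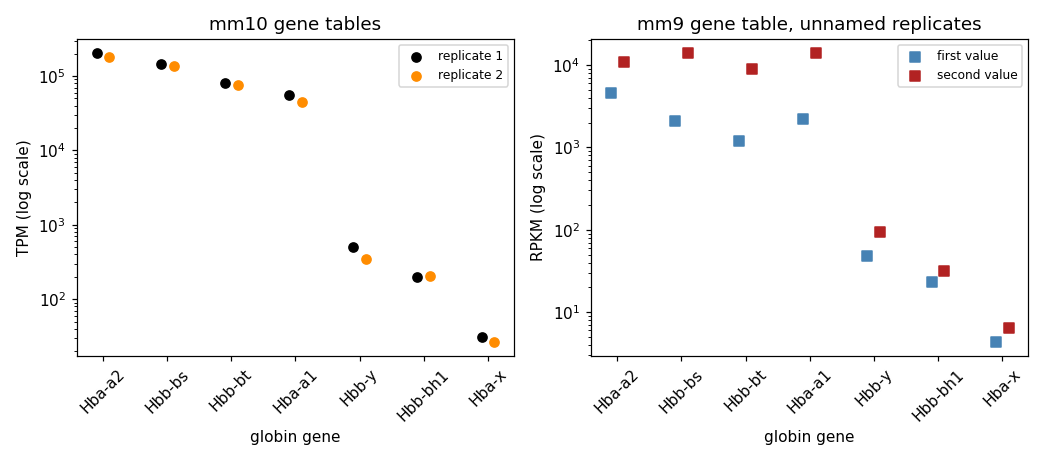
Globin genes in the mm10 gene tables (left, TPM per replicate) and in the mm9 gene table (right, RPKM, 2 values of unnamed replicates), both on log axes. The mm9 values of Hbb-bs are 2077 and 13867 RPKM, while its mm10 values are 145778 and 137870 TPM.

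Globin and hepatocyte genes also held large shares of the mm9 splice junction reads. Junctions inside Hbb-bs held 7.91% and 6.87% of the junction reads of the first and second replicate of the list, those inside Hba-a1 8.04% and 6.59%, those inside Alb 2.70% and 3.07%, and those inside Afp 2.02% and 2.32%. The list holds 1024689 junctions with 194969941 reads. Of these, 174152 carry a flag that in every case meant both ends at ENSEMBL exon boundaries, and they held 84.6% of the reads. The 850537 without the flag had a median of 1 read, and 590534 of them rested on 1 read. With an irreproducibility value of at most 0.1, 202342 junctions were left, 55236 of them unflagged.

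Most unflagged junction reads were aligned across neighbouring globin copies. The copies of each pair are nearly identical in sequence, so these alignments do not show that RNA was spliced between the genes. Junctions that start in Hba-a1 and end in Hba-a2, and those that start in Hbb-bt and end in Hbb-bs, held 13353479 and 12311755 reads, together 85.5% of all unflagged reads. The most used ran over mm9 chromosome 11, 32184129 to 32197079, with 8734881 reads, and over chromosome 7, 110961299 to 110975961, with 7305877 reads, and both ends of each lay on exon boundaries. These were singled out after their values were seen.

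Contigs are stretches of continuous mm9 signal that the authors listed for both replicates together, and the highest included some of the genes named above. The highest level, 7460, was at Hbb-bs (mm9 chromosome 7, 110972597 to 110977107), and the Hbb-bt, H19 and Alb loci were among the 12 highest with levels of 2740, 2340 and 1700. Also among the 12 were a contig over an exon of Gm23935 (level 4290) and a contig of 5920 bases antisense to a gene (level 3410). The rest were short contigs outside annotated genes or exons. No contig over Hba-a1, Hba-a2 or Afp was among the 12. Of 602461 contigs, 124495 (20.7%) overlapped an ENSEMBL exon on their strand by at least 1 base; these covered 208 Mb of 439.6 Mb and held 91.7% of the summed level times length. A further 292060 lay inside genes without touching an exon, at a median level of 0.0570 against 0.543 for exonic contigs, 55842 were antisense to a gene and 130064 lay outside genes. Of 66311 Cufflinks gene models, 41376 overlapped an ENSEMBL gene on the same strand, and of the 20127 outside genes 140 had an RPKM of at least 1 in both replicates.

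Spike-in RNAs, synthetic ERCC transcripts added to each sample, took 2.66% of expected counts in replicate 1 and 3.27% in replicate 2, or 2.58% and 3.34% of TPM. Of 96 spike-ins, 60 had at least 100 counts in total, and their TPM values spanned 0.195 to 8255 with a Pearson r of 0.9995 and a Spearman rho of 0.999 between the libraries on the log2 scale. Relative to genes, their median log2 ratio, replicate 2 over replicate 1, was 0.22, with an SD of 0.14 among spike-ins.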

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

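The tests of library depth for the muscle genes and of a true difference for the mm9 globins were chosen after the results were seen; a group of 2 allows no outlier test, and no second group exists to compare effects with. Expected counts on phiX174, the bacteriophage whose DNA is used as a sequencing control, stand in the gene tables beside the mouse genes and were used in no comparison. They made up 0.624% of all expected counts in replicate 1 (95% exact interval 0.623 to 0.626%) and 0.124% in replicate 2 (0.123 to 0.124%), far above what a count of 0 allows.

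Muscle genes were higher in replicate 1. A skeletal muscle list written apart from the fixed lists, with 22 genes that none of them holds, had a median log2 ratio of 3.42 in favour of replicate 1, and all 20 tested members were higher there; Mylpf was at 41.4 and 11.7 TPM and Acta1 at 17.3 and 1.63 TPM, while Tnnc1, the most abundant, was at 36.1 and 24.9 TPM. Library depth is argued against, since 73.3% of the adjacent tissue list (11 of 15 members) had more raw counts in the shallower library. A trend with GC content or gene length is argued against too: with it removed the median was 2.44, against 2.54 before, over the 11 members with enough counts. Carry-over of neighbouring tissue stays open and is a candidate explanation: epidermis (-1.41), cartilage and bone (-0.55) and nervous system (-1.06) genes had negative ratios of replicate 2 over replicate 1 beyond their random ranges, while heart (-0.19) and gut and pancreas (-0.15) genes lay within theirs. Over the members with enough counts, the first group were nearer 0, at -0.39 for epidermis (4 genes), -0.40 for cartilage and bone (8) and -0.50 for nervous system (5). No biological explanation was tested.

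Xist and the Y-linked genes differed in opposite directions. A trend with GC content or gene length is argued against, since the absolute log2 ratio of Xist was 1.87 with it removed. A different share of male embryos in the pools stays open: X-linked genes that escape inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x), a test added when the first proved thin, had a median log2 ratio -0.20 relative to other X-linked genes, and all 4 were lower in replicate 2, but 8.76% of random sets of 4 X-linked genes lay as low. The first test rested on 1 further Y-linked gene, Gm29650 (9 and 45 counts, log2 ratio 1.65), too few to decide. If the shares of the sexes were the whole cause, Xist and the Y-linked genes would put male RNA at 26.7% in replicate 1 and 79.8% in replicate 2. Differences between the pools other than in the share of male embryos were not tested.

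The adult globins had a summed RPKM in the mm9 gene list that was 4.72 times as high in the second replicate as in the first. A split of reads between near-identical copies is argued against, since sums over both copies still differed by a factor of at least 3.63. A true difference between the samples is argued against, since summed mm10 TPM differed by a factor of 1.11. Loss at the mm9 gene quantification stays open and may explain it: the adult globin share of mm9 junction reads was 30.9% and 26.1%, a factor of 1.19. No direction is read from this, since the numbering of the junction reads and of RPKM seems crossed: Actc1 had 3607 and 265 junction reads but 0.246 and 6.74 RPKM.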

How the results depend on the processing

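The settings of contig overlap by length, of gene ratios under other scalings and of protein-coding genes alone were chosen after seeing the data, and the others before. Other scalings were run for the medians of the fixed lists and for named genes with large ratios, not for every gene called. None of those genes, and no ratio between gene groups, changed its direction; of the fixed lists, the medians of niche factors (members with at least 100 counts) and of fetal RNA-binding and chromatin genes (library totals), both inside their random ranges, changed sign. Of the lists added later, trophoblast, outside its range at 1.18, turned to -0.46 over members with at least 100 counts. Of the values that answer a comparison, 34 were counted as kept and 21 as moved, by rules that differed with the kind of value. Means over the libraries were held to their SD, and counts and the coefficient of variation to 1.5-fold. The r of the libraries was held to an interval that takes genes as independent. With 2 libraries, leaving 1 out always stays within the SD, so for values held to it that setting tests nothing. For lists and genes 229 were kept and 53 moved. There, list levels were held to the SD, list ratios to the random range and gene ratios to their sign alone. With members of at least 100 counts, 1 list (cholangiocyte) left and 1 list (T and NK) entered the range of random lists. Unless said otherwise, the cause was not tested.

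With mm9 RPKM in place of TPM, the log2 ratio of adult over embryonic globins was 6.51 ± 1.39 for beta (46.1-fold and 181-fold in the replicates of that list) and 11.24 ± 0.914 for alpha (1547-fold and 3789-fold), fetal over mature hepatocyte genes 9.38, and erythroid over fetal hepatocyte genes -1.36. With members of at least 1 TPM alone, the last pair were 4.05 and -1.15, by the removal of low members; with the mean of log2(TPM + 0.1) they were 6.83 and -0.0664, and with the mean of log2(TPM + 1) 5.51 and -0.18, so the size of the erythroid gap rests on the median. With expected counts the 10 highest entries, spike-ins and phiX174 among the candidates, took 30.9%, by construction, as counts are not divided by gene length. At 5 TPM 7414 genes were detected, by construction.

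Pearson r of the libraries was 0.997 with a pseudocount of 1, 0.979 over genes with at least 1 TPM in either library and 0.994 for FPKM. That of mm9 and mm10 values was 0.815 over genes above 1 in both and 0.909 with a pseudocount of 1. The negative binomial exact test left 471 genes differing between the libraries; over genes with at least 100 counts it left 223 higher in replicate 1 and 26 higher in replicate 2, with a biological coefficient of variation of 0.160. Its dispersion comes from the libraries it compares, so the differences under test set their own error. The same main transcript was found for 94.2% of genes at 1 TPM and 96.5% at 20 TPM. Contigs with at least 50% of their length in an exon were 10.3% of all, by the stricter overlap.

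No paired analysis was possible because the libraries form 1 group. DESeq2's test was not run, as it gives none with 1 library on each side. Depth limits the lowest genes: with 3 counts as the limit for 0, Cd8a and Fgf21 were not detected, which bounds their level and does not show that they are absent.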

Other observations

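The lists and values here were chosen after the data were seen. Of the interferon response list, 11 of 12 tested members were higher in replicate 2, with a median log2 ratio of 0.40 (random lists -0.12 to 0.12); Bst2 was at 42.0 and 52.5 TPM and Isg15 at 9.35 and 15.2 TPM. Of the trophoblast list, 5 of 11 tested members were higher in replicate 2 and 1 in replicate 1, with a median of 1.18 (random lists -0.63 to 0.26). That median rests on members with few counts (median level 0.0400 ± 0.0283 TPM), and over the 3 members with at least 100 counts it was -0.46, so the list has no firm direction. Of the epidermis list 6 of 9 tested members were higher in replicate 1, of cartilage and bone 5 of 14, of nervous system 8 of 12, of heart 2 of 6 and of gut and pancreas 1 of 5, and none was higher in replicate 2.

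Gm42418 took 0.373% of the expected counts on genes in replicate 1 and 1.52% in replicate 2. Without the junctions aligned across globin copies, junctions not at annotated pairs of exon boundaries held 2.57% of the junction reads that remain. The first RPKM of the mm9 gene table had a Spearman rho across genes of 0.927 with TPM of replicate 1 and 0.945 with TPM of replicate 2, and the second had 0.931 with replicate 2 and 0.943 with replicate 1. The log ratios of the second over the first RPKM and of replicate 2 over replicate 1 TPM had a Pearson r of -0.54 across 8259 genes, so the numbering of the mm9 values was not taken to be that of the libraries.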
